A study of Mus musculus with 30 samples.

How the data were processed

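RNA from cell cultures labelled as mouse leg muscle was measured at 0, 4, 12, 24 and 48 h, with 3 replicates per hour, on the A and the B chip of an Affymetrix set, 30 arrays in all. Hour, chip and replicate number came from the sample titles. The deposited values are linear probe set intensities, 1 column per array, with replicates not pooled. Per the labels, the RNA was processed by the manufacturer's standard protocol. The software, the algorithm that summarised probes into probe sets, the detection calls and the genome build are not given in the sources used here. From the deposited intensities themselves, the 2%-trimmed mean was 500.1 to 500.2 on all A arrays and 500.1 on all B arrays, so each array had been scaled as a whole to a common level, and no further scaling was applied. Intensities ran from 0.1 to 25728.3 on A and from 0.2 to 113994.1 on B. Such scaling fixes the mean of each array, so a change in total RNA per cell leaves no trace, and a few very bright probe sets can shift all others slightly.

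The A chip held 22690 probe sets and the B chip 22575, each with 64 control probe sets, which were left out of the tests. Probe sets were named through a table taken from GEO's platform annotation, with symbols updated through gene identifiers in a RefSeq table of GRCm38.p6, which changed 0 symbols. On A, 20393 probe sets had 1 gene (12394 genes), 691 had several and 1555 were unnamed here, and on B the numbers were 14674 (9612 genes), 245 and 7605. Of the identifiers, 29 on A and 175 on B were not in the RefSeq table and kept the annotation's name. Probe sets with several genes were tested but not named. Because no build is named, no coordinates are printed.

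Intensities were transformed to log2 after adding a pseudocount set at the 20th percentile of each chip, 29 on A and 54 on B. A log2 change is therefore on the log2(intensity + pseudocount) scale and understates the change of dim genes. The upper 60% of probe sets by mean log2 value were tested, 13576 on A and 13507 on B. Each chip was fitted on its own in limma 3.58.1 (lmFit, contrasts.fit, and eBayes with an intensity trend) in R 4.3.3, over its 15 arrays with hour as the factor, so that all hours share an estimate of the spread. The comparisons were 4, 12, 24 and 48 h each against 0 h, the steps from 4 to 12, 12 to 24 and 24 to 48 h, and a moderated F test over all hours. P-values were adjusted by Benjamini-Hochberg within each chip and comparison, all tests were two-sided, and a probe set was called at an adjusted p under 0.05. The same arrays at 0 h enter every comparison against 0 h, so those comparisons share their chance deviations. With 3 arrays against 3 an exact permutation test of a single gene cannot go below a two-sided p of 0.1, so the model's pooled spread carries the calls.

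For gene counts and lists each gene was represented by 1 probe set, the brightest one, from A where any of its probe sets was tested there and otherwise from B. The design, the alternatives, 32 pathway lists and 7 lists of markers of other cell types were fixed before the data were examined. A list's calls were counted over all probe sets and adjusted over the list alone. Its shift was tested with limma's camera on A, with a preset correlation of 0.01, for lists with at least 5 genes there, with Benjamini-Hochberg adjustment over the lists and the 4 comparisons against 0 h. Over all arrays no call of camera held with an estimated correlation, with or without replicate 3 as a batch term. In replicates 1 and 2 alone 21 of 63 calls did. The genes named were fixed by rule. The first part took, for each comparison with 0 h, the called genes with the largest log2 changes whose arrays did not overlap those at 0 h. At 48 h it took 10 rises and 10 falls on A and 4 and 4 on B, and at 4, 12 and 24 h 5 and 5 on A and 2 and 2 on B. The second part took 16 genes whatever their test (Myog, Myod1, Myf5, Myf6, Mef2c, Cdkn1a, Ccnd1, Id1, Id2, Id3, Myh3, Ckm, Acta1, Chrna1, Top2a and Igf2). The third took, for each list described, up to 4 members with the smallest adjusted p and up to 2 that went against the majority.

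The alternatives were quantile normalization, median centring, other pseudocounts (0.5 and 4 times the one used, and 1), no filter or the upper 40%, the replicate number as a block, only the arrays of the hours compared, eBayes without trend, and array quality weights. Others were an added threshold of 2-fold, another probe set of a named gene, the mean of a gene's probe sets for lists, and leaving out each array in turn. Replicate 3 as a batch term and replicates 1 and 2 alone were added after the data were seen. To describe the split, replicate 3 was compared with replicates 1 and 2 in a limma fit with hour as a further factor, over all hours.

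The fits were tested on simulated data built from the real means and spread, with 100 probe sets changed at each fold between 0 h and 48 h. With the replicate 3 difference put in, 59% of 2-fold and 93% of 4-fold changes were recovered on A among 13576 probe sets, with 2 false calls, and 41% and 79% on B among 13507, with 1 false call. With replicate 3 as a batch term the shares were 87% and 98% on A with 9 false calls, and 54% and 86% on B with 5. The simulated probe sets were drawn independently, and each change had the same size in all 3 arrays at 48 h. In the real data genes were correlated (estimated correlation 0.359 for the mitosis list with the batch term). Real changes also differed in size in replicate 3, so real recovery and false calls can differ from these. The 100 probe sets present on both chips gave log2 changes from 0 h that correlated between A and B at r = 0.72, 0.66, 0.76 and 0.80 for 4, 12, 24 and 48 h, across probe sets, which are not independent replicates. An A and a B array of the same label can hold the same RNA, so B calls do not stand as independent of A calls. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.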

Results

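Transcript levels were measured with oligonucleotide arrays in cell cultures labelled as mouse leg muscle at 0, 4, 12, 24 and 48 h. Each hour had 3 replicates, and each replicate had 1 array of each chip of a 2-chip Affymetrix set, called A and B, which gave 30 arrays. The labels give neither the event that starts the clock at 0 h nor the medium, so the comparisons address how transcript levels differed between the hours and nothing more specific. They also do not say that replicates came from separate cultures or animals, so p-values measure only the spread between these arrays, which may be technical. Every A array had a trimmed mean intensity of 500.1 to 500.2 and every B array one of 500.1, and the array medians were 154.7 to 183.4 on A and 220.0 to 256.2 on B. No pair of arrays held identical values. The number of arrays, 3 per hour on each chip, limits the precision.

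The arrays of replicate 3 stood apart from those of replicates 1 and 2 at every hour. Cell division genes were higher in replicate 3: all 44 measured genes of the mitosis list and 33 of 36 of the S phase list passed the test, with median log2 differences of 1.01 and 0.91. Genes of cholesterol synthesis were also higher (14 of 19), whereas 6 of 8 muscle transcription factors, among them Myog and Myod1, were lower. Crabp1, which encodes a retinoic acid binding protein, had a mean intensity of 17.09 in replicates 1 and 2 and 2059 in replicate 3, and Cthrc1, a secreted protein of the matrix, had 6567 and 98.2 in the same order. Cd34 was higher in replicate 3 (log2 difference 2.67) and Rgs5, a pericyte gene, lower (log2 difference -3.96). These 4 genes were picked after their values were seen. In the limma fit, 4606 of 13576 tested A probe sets and 2000 of 13507 tested B probe sets differed between replicate 3 and the others. The first principal component held 36.8% of the variance on A and 19.6% on B. Because of this split, which was seen only in the data, the number of called probe sets in each comparison is also given with replicate 3 as a batch term (the batch fit) and over replicates 1 and 2 alone. Both were chosen after the arrays were seen.

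**Figure D1:**
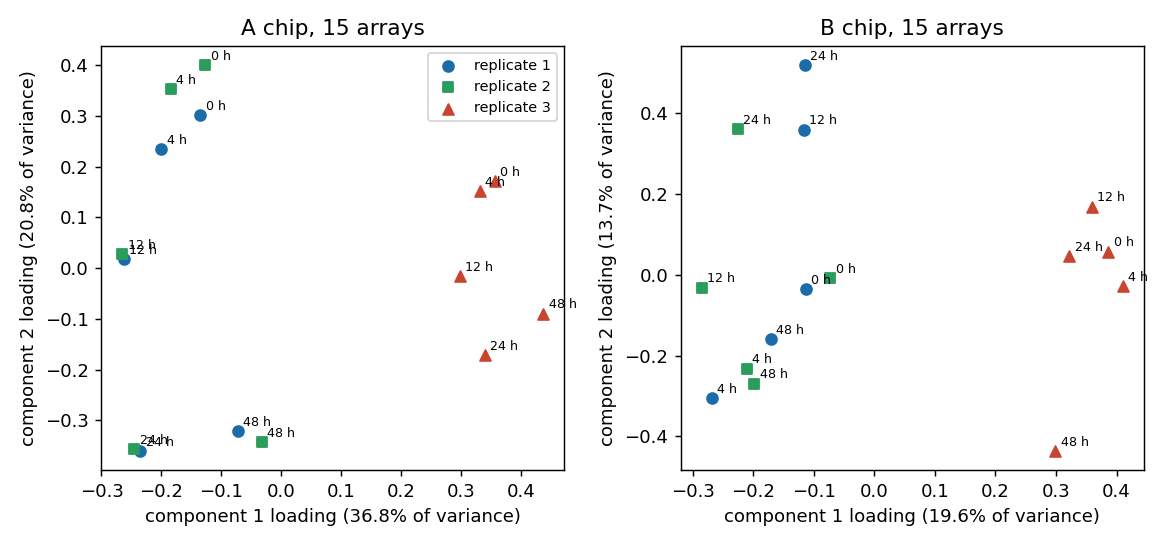
Loadings of each array on the first (x axis) and second (y axis) principal components of the log2 intensities, for the A chip and the B chip, with points coloured by replicate and labelled by hour. On the A chip the replicate 3 arrays load between 0.298 and 0.437 on the first component and all arrays of replicates 1 and 2 load below 0.

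Transcript levels differed between the hours for 267 A probe sets and 121 B probe sets in the moderated F test over all 5 hours (adjusted p under 0.05). Of the 267 on A, 92 had their highest mean at 24 h, 83 at 48 h and 64 at 0 h, and on B the numbers were 46, 39 and 21 of 121. The batch fit called 1895 on A and 898 on B, and replicates 1 and 2 alone gave 2376 and 1059. Single arrays of replicates 1 and 2 moved the A count most. It was 96 and 81 without the 0 h arrays of replicates 1 and 2 and 156 and 134 without their 4 h arrays. It was 88 and 107 without their 24 h arrays, and 115 and 118 without their 48 h arrays. On B the count was 54 and 62 without the 0 h arrays of replicates 1 and 2, 58 and 58 without their 4 h arrays, and 68 without the 12 h array of replicate 1. Without their 24 h arrays it was 30 and 32, and without their 48 h arrays 71 and 40. Without the 24 h or the 48 h array of replicate 3 it was 195 or 185.

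At 4 h no single gene passed the test against 0 h, and over all arrays the list calls of camera held with its preset correlation alone. All 19 measured genes of cholesterol synthesis and uptake had lower means at 4 h than at 0 h, with a median log2 difference of -0.47. For Cyp51, an enzyme of that pathway, the mean intensity was 1698 ± 177.1 (SD, n = 3) at 0 h and 1095 ± 396 at 4 h (adjusted p = 0.88, and 0.13 in the batch fit and 0.028 in replicates 1 and 2 alone). Limma's set test camera called the list lower (adjusted p = 1.17e-08 with the preset correlation; adjusted p = 0.445 with an estimated correlation), and limma called 0 of its genes, also when adjusted over the list alone (4 had an unadjusted p under 0.05). Adjusted over the list alone, 10 of the 19 were lower in the batch fit and 14 in replicates 1 and 2 alone, where 5 passed over all probe sets. Those fits gave the list adjusted p = 0.163 and 0.00897 with an estimated correlation. In replicate 3, whose arrays stand apart, 14 of these 19 genes were higher than in replicates 1 and 2. All 10 developmental isoforms of the sarcomere, the contractile unit of muscle, had higher means at 4 h (median log2 difference 0.33, camera adjusted p = 2.41e-06; adjusted p = 0.409 with an estimated correlation). So did 18 of 20 genes of the amino acid response (median 0.34, 4.91e-07; adjusted p = 0.445 with an estimated correlation). In neither list did limma call a gene, also when adjusted over the list alone (4 and 5 had an unadjusted p under 0.05). Adjusted over the list alone, 4 developmental isoforms and 1 amino acid response gene were higher in the batch fit. In replicates 1 and 2 alone 5 and 10 were higher and 1 amino acid response gene lower, and 1 of each list was higher over all probe sets. There the lists had adjusted p = 0.124 and 0.0435 with an estimated correlation. The cytosolic ribosomal proteins had a median of 0.23 with 21 of 25 positive (camera adjusted p = 4.09e-12; adjusted p = 0.222 with an estimated correlation), and 2, Rpl7 and Rpl4, passed when adjusted over the list alone (1 in the batch fit, none in replicates 1 and 2 alone). Quantile normalization turned that shift downwards (adjusted p = 0.606), so its direction depends on the scaling. S phase genes had a median of -0.25 (camera adjusted p = 0.00459; adjusted p = 0.738 with an estimated correlation). That shift turned to the other direction without the 0 h array of replicate 3 (0.984) and was not called without the 4 h arrays of replicate 1 (0.48) or 2 (0.278). Those 3 fits had no batch term, so replicate 3, where S phase genes were higher, weighed more at 4 h than at 0 h. The S phase shift had camera adjusted p = 5.51e-09 in the batch fit and 1.4e-08 in replicates 1 and 2 alone (adjusted p = 0.207 and 0.0685 with an estimated correlation). Limma called 0 of 13576 A probe sets and 0 of 13507 B probe sets, and 671 and 732 had an unadjusted p under 0.05. In any comparison chance alone gives about 679 such probe sets on A and 675 on B. With replicate 3 as a batch the count was also 0 on both chips, and replicates 1 and 2 alone gave 24 on A and 0 on B.

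At 12 h the genes of the muscle contractile apparatus had higher means than at 0 h, and a single probe set passed the test. All 10 developmental sarcomere isoforms passed when adjusted over the list alone, though 0 did over all probe sets, with a median log2 difference of 0.66. Myh3, the embryonic myosin heavy chain, had 4075 ± 1013 (SD, n = 3) at 0 h and 8108 ± 358.8 at 12 h (adjusted p = 0.21, but 0.016 in the batch fit and 0.00027 in replicates 1 and 2 alone). Adjusted over the list alone, 5 of 8 adult fast isoforms, 8 of 26 genes of shared sarcomere structure, 7 of 18 genes of excitation-contraction coupling and 3 of 15 genes of muscle energy supply were higher, with medians of 0.72, 0.59, 0.64 and 0.59. Camera called these lists higher (adjusted p from 8.54e-12 for the developmental isoforms to 2.08e-08 for energy supply; adjusted p = 0.172 with an estimated correlation for all but energy supply, which had adjusted p = 0.216 with an estimated correlation). Over all probe sets 1 developmental, 2 fast, 4 shared structure, 5 coupling and 2 energy genes were higher in the batch fit, and 7, 4, 15, 10 and 6 in replicates 1 and 2 alone. In the latter shared structure and coupling each had adjusted p = 0.0102 with an estimated correlation, and energy supply had adjusted p = 0.042 with an estimated correlation. The developmental and fast lists did not hold there (adjusted p = 0.0656 and 0.059 with an estimated correlation). In replicate 3, 12 of the 26 shared structure genes, 9 of the 18 coupling genes, 4 of the 15 energy genes and 1 fast isoform were lower than in replicates 1 and 2, and 3 shared structure genes, 1 developmental and 2 fast isoforms were higher. S phase and mitosis genes had medians of -0.45 and -0.58 with no gene called by limma, also when adjusted over the list alone (3 and 1 had an unadjusted p under 0.05). Camera called both lower (adjusted p = 1.04e-06 and 7.76e-07; adjusted p = 0.668 and 0.676 with an estimated correlation). These are the lists that were higher in replicate 3, and without the 0 h array of replicate 3 neither was called (0.0902 and 0.0649). In the batch fit 4 S phase genes and 5 mitosis genes were lower, and in replicates 1 and 2 alone 6 and 19 (adjusted p = 0.0427 and 0.039 with an estimated correlation).

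The probe set called at 12 h, named after its value was seen, belongs to Vegfc, a growth factor of lymphatic vessels (B chip). Its mean fell from 1961 ± 448.1 to 469 ± 157.5 (SD, n = 3), a log2 change of -1.97 with SE 0.27 and adjusted p = 0.037. It was no longer called without the 0 h arrays of replicates 1 or 2 or the 12 h arrays of replicates 2 or 3, and the A chip probe set for Vegfc, at -1.56, was not called (adjusted p = 0.183). Limma called 0 of 13576 A probe sets (890 with an unadjusted p under 0.05) and 1 of 13507 B probe sets (858). In the batch fit the counts were 143 on A and 44 on B, and replicates 1 and 2 alone gave 568 and 84. Without the 12 h array of replicate 3 the A count was 1.

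At 24 h genes of muscle contraction and of muscle energy supply rose, and among the genes that fell were Id3, Myf5 and Smoc2. The largest rises on the A chip were those of Lmcd1, a LIM domain cofactor (from 146.4 ± 52.32 to 1231 ± 334.2, SD, n = 3), Fn3k, a kinase that repairs glycated proteins, and Myh8, the perinatal myosin heavy chain (from 87.63 ± 77.69 to 537.1 ± 211.7). Next came Cox6a2, the muscle form of a cytochrome oxidase subunit, and Fgf21, a secreted metabolic hormone (from 552.3 ± 187.8 to 3025 ± 1275). The log2 changes were 2.85, 2.60, 2.41, 2.41 and 2.34, with adjusted p = 0.002, 0.023, 0.033, 0.0033 and 0.013. Another Fn3k probe set, on B, had 0.9 and was not called (adjusted p = 0.44). On the B chip Ankrd23, a muscle ankyrin repeat protein, rose from 180.8 ± 221.7 to 1772 ± 112.3 (log2 change 3.37, SE 0.63, adjusted p = 0.018), and Cfap52 rose with a log2 change of 2.48 (adjusted p = 0.0091). Another Cfap52 probe set on B had 1.58 and was not called (adjusted p = 0.21). Smoc2, a secreted calcium-binding protein of the matrix, fell most, from 1237 ± 139.1 to 101.2 ± 58.19 (log2 change -3.38, SE 0.31, adjusted p = 0.00022). It was followed by Col2a1, the cartilage collagen (-2.77, 0.0038), Rgs4, a regulator of G protein signalling (-2.40, 0.022), Atoh8, a helix-loop-helix factor (-2.11, 0.002), and Islr, a secreted leucine-rich repeat protein (-2.08, 0.0073). On B the largest falls were those of Gm1673 (-1.61, 0.0099) and Nrn1, a neurite growth factor (-1.57, 0.0048). All of these largest rises were smaller in replicate 3, 1 array per hour, than in replicates 1 and 2. Lmcd1 had log2 changes of 1.92 and 3.31 and Fn3k 1.07 and 3.37 in that order. The falls went both ways, with Atoh8 at -2.67 and -1.83 and Col2a1 at -1.45 and -3.43 in the same order.

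Within the lists fixed beforehand, 7 of 10 developmental sarcomere isoforms rose at 24 h (9 adjusted over the list alone), with Myh3 going from 4075 ± 1013 to 9790 ± 523.6 (SD, n = 3) and a list median log2 change of 1.00. Of the adult fast isoforms 5 of 8 rose (7 adjusted over the list alone), among them Myh1, a fast myosin heavy chain, from 1685 ± 687.2 to 5233 ± 380.6. Myh7 and Myoz2 rose, 2 of 5 slow or cardiac isoforms (3 adjusted over the list alone). Both were higher in replicate 3, as were Tpm3 of that list, 1 developmental isoform (Myh8) and 2 fast isoforms, while 1 slow or cardiac and 1 fast isoform were lower. Of 26 genes of shared sarcomere structure 9 rose (18 adjusted over the list alone), including Csrp3 (1.67) and the M-band protein gene Myom2 (2.27), and 12 of the 26 were lower and 3 higher (Csrp3, Smyd1 and Myot) in replicate 3. Excitation-contraction coupling, the release of calcium on stimulation, had 8 of 18 genes rise (15 adjusted over the list alone), such as Casq2, the calcium store protein, from 1888 ± 957.6 to 7011 ± 1177, and 9 of the 18 were lower in replicate 3. Muscle energy supply had 9 of 15 rise (11 adjusted over the list alone), including the creatine kinase gene Ckm from 923.3 ± 361.4 to 2782 ± 544.1, and 4 of the 15 were lower in replicate 3. Another Ckm probe set, on B, had a log2 difference of 0.12 and was not called (adjusted p = 0.89), where the one used had 1.61. Camera called the developmental, fast, shared structure, coupling and energy lists higher (adjusted p = 4.09e-12, 1.63e-09, 1.54e-12, 1.99e-13 and 4.09e-12), and each had adjusted p = 0.172 with an estimated correlation. The slow or cardiac list had too few genes on A for camera. Of 17 genes of fusion and sarcolemma Cav3 and Bin1 rose (5 adjusted over the list alone; camera adjusted p = 1.5e-05; adjusted p = 0.172 with an estimated correlation), and 8 of the 17 were lower and 2 higher in replicate 3. With the batch term 9 developmental, 6 fast, 3 slow or cardiac, 20 shared structure, 14 coupling, 11 energy and 5 fusion genes were higher. Replicates 1 and 2 alone gave 9, 6, 3, 20, 15, 11 and 7. There adjusted p = 0.00897 with an estimated correlation for shared structure and for coupling, and adjusted p = 0.0299 and 0.0363 with an estimated correlation for energy and fusion. The developmental and fast lists did not hold (adjusted p = 0.0591 and 0.0568 with an estimated correlation).

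Among the regulators fixed beforehand, Mef2c, a transcription factor of muscle genes, rose from 1148 ± 456.6 to 4279 ± 1137 (SD, n = 3) at 24 h (log2 change 1.90, SE 0.30, adjusted p = 0.0054). Its log2 change was 2.43 in replicates 1 and 2 and 0.84 in replicate 3. Myog and Myod1, which direct muscle differentiation, had log2 differences of 0.09 and -0.19 (adjusted p = 0.8 and 0.73), and Myog stood at 10320 ± 675.5 at 0 h already. Of the 8 muscle transcription factors 2 rose, Mef2c and Mef2d (2 up and 1 down adjusted over the list alone), and 6 were lower in replicate 3. Of 15 proliferating myoblast and Notch genes 3 fell, Id3 and Id1, inhibitors of helix-loop-helix factors, and Myf5, a determination factor (7 adjusted over the list alone; median -0.67; camera adjusted p = 7.36e-05; adjusted p = 0.172 with an estimated correlation). Id3 fell from 4171 ± 1093 to 1069 ± 190.4, a log2 change of -1.92, and 8 of the 15 were lower and 2 higher in replicate 3. Of these 15 genes 8 were lower in the batch fit and 9 in replicates 1 and 2 alone (adjusted p = 0.0346 with an estimated correlation). Of the 8 transcription factors both fits called 3 higher and 1 lower. The other fixed genes had log2 differences of -1.24 (Id2), -0.61 (Ccnd1), 0.56 (Acta1), 0.26 (Cdkn1a), 0.24 (Igf2), 0.17 (Chrna1) and 0.16 (Myf6), and none was called. Top2a, which untangles DNA in dividing cells, had -0.82 (adjusted p = 0.54). The batch fit called Id2, Ccnd1, Acta1 and Top2a (adjusted p = 0.0015, 0.0046, 0.017 and 0.0067), and so did replicates 1 and 2 alone (0.0029, 0.0013, 0.016 and 0.00023).

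Cell division genes had lower means at 24 h than at 0 h. All 44 mitosis genes were below their 0 h mean (median -0.67), though limma called 0, also when adjusted over the list alone (5 had an unadjusted p under 0.05). Of 36 S phase genes 1 fell, Ccne1 (1 adjusted over the list alone; median -0.62). Camera called both lists lower (adjusted p = 3.53e-05 for mitosis and 1.19e-05 for S phase; adjusted p = 0.684 and 0.676 with an estimated correlation). Replicate 3 was higher in 77 of these 80 genes at all hours together. The mitosis call was lost without the 0 h array of replicate 3 (adjusted p = 0.064). In the batch fit 30 mitosis and 27 S phase genes were lower, and in replicates 1 and 2 alone 32 and 25 (adjusted p = 0.0467 with an estimated correlation for each). Among other lists, the amino acid response had 3 of 20 genes rise (4 up and 1 down adjusted over the list alone), Slc7a5, Atf5 and Asns. Slc7a5, an amino acid transporter, went from 1024 ± 569.7 to 3203 ± 571.2 (SD, n = 3), and camera called the list (adjusted p = 3.48e-06; adjusted p = 0.492 with an estimated correlation). The small heat shock proteins Hspb7, Hspb3 and Hspb2 rose among 15 heat shock genes (4 adjusted over the list alone; camera adjusted p = 9.7e-05; adjusted p = 0.172 with an estimated correlation). Nfkbia, the inhibitor of NF-kappaB, fell from 4709 ± 360.9 to 2109 ± 99.42 and Csf1 fell too. They were the called genes among 10 cytokines and NF-kappaB targets (4 adjusted over the list alone; camera adjusted p = 0.0316; adjusted p = 0.445 with an estimated correlation). That camera call was lost without the 0 h array of replicate 3 (0.153) or the 24 h array of replicate 2 (0.0668). In replicate 3, 7 amino acid response genes and 6 of these NF-kappaB list genes were higher, and 3 heat shock genes were higher and 4 lower. The batch fit had 6 amino acid response genes higher and 1 lower, 5 heat shock genes higher and 6 NF-kappaB list genes lower. Replicates 1 and 2 alone had 10 higher and 1 lower, 6 higher and 5 lower in the same order (adjusted p = 0.0713, 0.0355 and 0.186 with an estimated correlation).

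Limma called 218 A probe sets higher and 144 lower at 24 h than at 0 h, and 80 B probe sets higher and 35 lower, and 187 of the 362 on A changed at least 2-fold. Over 12446 genes, 1 probe set each, 197 rose and 117 fell. The batch fit called 1770 on A (814 higher, 956 lower) and 556 on B (312 and 244) and kept all 362 and 115. Replicates 1 and 2 alone gave 2036 (885 and 1151) and 696 (375 and 321). With each array centred on its median the A split was 321 higher and 104 lower, so whether rises outnumber falls on A depends on the fit. Across all tested A probe sets, which are not independent replicates, the 24 h differences in replicates 1 and 2 and in replicate 3 had r = 0.46. The A count was 137 and 82 without the 0 h arrays of replicates 1 and 2, 60 and 67 without their 24 h arrays and 636 without that of replicate 3, and on B these counts were 36, 34, 34, 37 and 211. Of the 64 calls among named genes at 24 h, 25 and 29 were kept without the 24 h arrays of replicates 1 and 2.

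**Figure D2:**
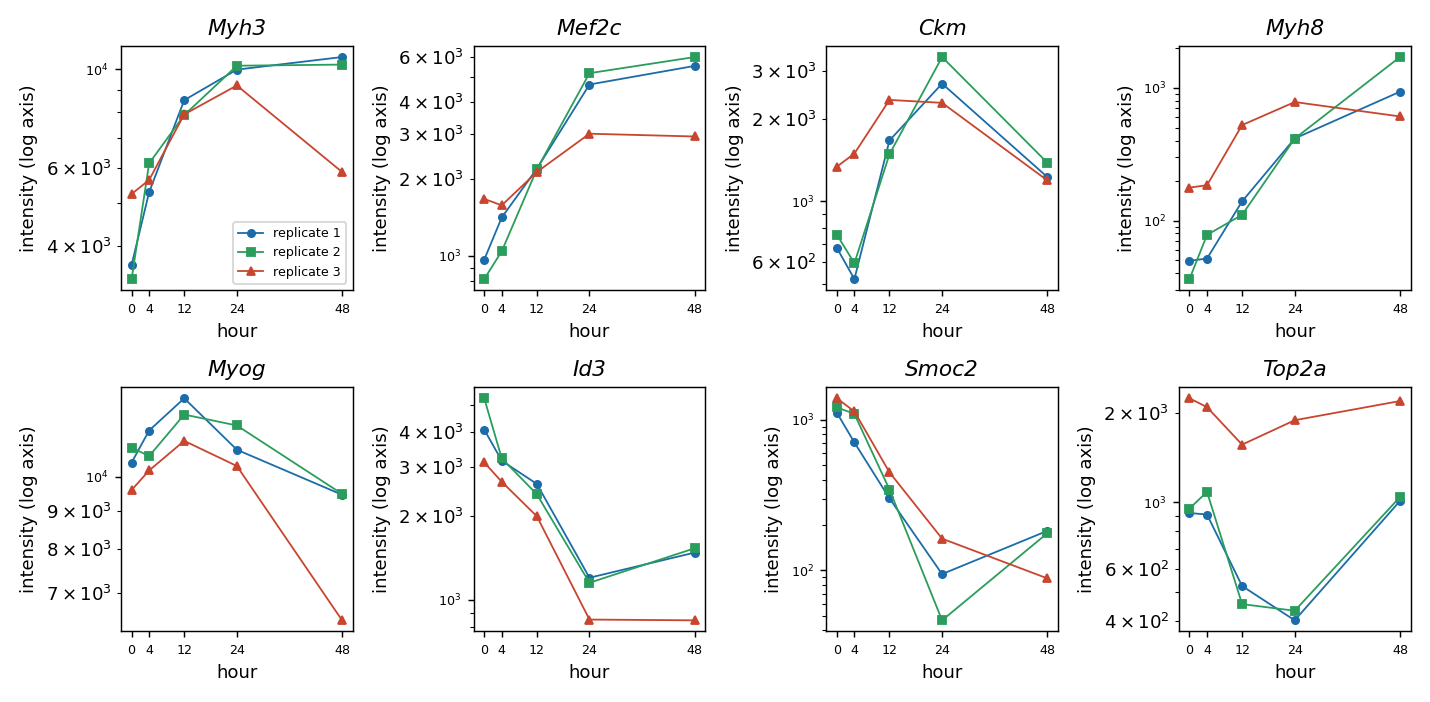
Intensity (log axis) of 8 genes at each hour, with points for the 3 replicates joined by replicate number; the numbers are not shown to pair the cultures. Myh3, Mef2c and Myh8 have higher means at 24 h and 48 h than at 0 h, Id3 and Smoc2 have lower ones, Myog had 10320 at 0 h and 8455 at 48 h, and Top2a lies apart in replicate 3.

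At 48 h the largest rises included genes of the contractile apparatus. Myh8 rose from 87.63 ± 77.69 to 1083 ± 563.6 (SD, n = 3; log2 change 3.33, SE 0.56, adjusted p = 0.0093), ahead of Lmcd1 (2.96, 0.0022) and Fn3k (2.80, 0.021). The other Fn3k probe set, on B, had 1.1 and was not called (adjusted p = 0.23). Myot, a Z-disc protein gene, rose from 69.7 ± 52.97 to 564.8 ± 130.5 (2.70, 0.013), and Cd36, a fatty acid transporter, from 43.13 ± 16.35 to 439.1 ± 168.6 (2.65, 0.0023). Dcx, a microtubule-binding protein of young neurons, rose from 74.53 ± 39.1 to 598.9 ± 164.7 (2.64, 0.012). Then came Myoz2 (2.60, 0.015), Actn2, the Z-disc actinin, from 822.7 ± 573.8 to 4722 ± 1743 (2.60, 0.0059), Cox6a2 (2.58, 0.0023) and Casq1 (2.52, 0.016). On B the largest were Ankrd23 (2.96, 0.033), Tecrl, from 156.7 ± 26.57 to 1772 ± 935.7 (2.94, 0.012), Mybpc1, a slow myosin-binding protein (2.26, 0.025), and 4930512H18Rik (2.24, 0.0038). The largest falls on A were those of Smoc2 (-2.87, 0.00071), Islr (-2.72, 0.0023), Atoh8 (-2.67, 0.0005), Col2a1 (-2.43, 0.0083), Cebpa, an adipocyte transcription factor (-2.06, 0.0099), and Vegfc, from 469.2 ± 109.8 to 97.7 ± 31.35 (-1.98, 0.0028). After these came Emilin1 (-1.79, 0.021), Id3 (-1.69, 0.0028), Tmem176a (-1.62, 0.02) and Plxnd1 (-1.55, 0.0023). On B Lrrc17 fell from 17930 ± 7820 to 3298 ± 813.8 (-2.34, 0.009), followed by Podxl2 (-2.27, 0.032), Sox8 (-1.64, 0.034) and Slc2a6 (-1.63, 0.027). In each pair of values in brackets the log2 change comes before the adjusted p.

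By list, 7 of 10 developmental isoforms, 6 of 8 fast isoforms, 3 of 5 slow or cardiac isoforms, 8 of 26 genes of shared structure, 8 of 18 coupling genes and 7 of 15 energy genes rose at 48 h. Adjusted over the list alone these counts were 9, 7, 3, 12, 12 and 7, and no gene of these lists fell. Camera called the developmental, fast, shared structure, coupling and energy lists higher (adjusted p = 1.01e-11, 1.05e-10, 7.65e-08, 1.43e-11 and 1.13e-09; with an estimated correlation adjusted p = 0.172, and adjusted p = 0.197 for shared structure). With the lists in the order first given, 9, 7, 3, 13, 12 and 8 genes were higher in the batch fit, with 1 shared structure gene lower, and 9, 7, 3, 19, 14 and 11 in replicates 1 and 2 alone. In the latter, adjusted p = 0.0467, 0.0102, 0.00897 and 0.0299 with an estimated correlation for fast isoforms, shared structure, coupling and energy. The developmental list did not hold (adjusted p = 0.0544 with an estimated correlation). In replicate 3, 12 shared structure genes, 9 coupling genes, 4 energy genes, 1 fast isoform and 1 slow or cardiac isoform were lower. Higher in replicate 3 were Myh7, Myoz2 and Tpm3 of the slow or cardiac list, Smyd1, Csrp3 and Myot of shared structure, Myh8, and 2 fast isoforms. Myh3 rose to 8927 ± 2657 (SD, n = 3; log2 change 1.10). Its log2 change was 1.57 in replicates 1 and 2 and 0.16 in replicate 3, so the rise was nearly absent there. Trdn, which anchors the calcium release channel, rose from 91.57 ± 33.01 to 561.9 ± 297.5, and Fabp3, a fatty acid carrier, from 170.4 ± 68.45 to 1040.0 ± 574.1. Ckm was at 1267 ± 102.1, a log2 difference of 0.51 that was not called (adjusted p = 0.54, and 0.26 in the batch fit), though replicates 1 and 2 alone called it (0.0028). The other Ckm probe set, on B, had -0.27 and was not called (adjusted p = 0.58). The acetylcholine receptor and synapse list had 2 of 11 genes rise, Erbb3 and Ncam1 (3 adjusted over the list alone). Its median of -0.11 and mean of 0.08 differ in sign, camera did not call it (adjusted p = 0.322), and 7 of the 11 were lower in replicate 3. The batch fit had 3 higher and 1 lower, and replicates 1 and 2 alone 1 higher and 2 lower. Other probe sets of Ncam1 had -0.42 and -0.09 where the one used had 1.02. At 24 h the same list had Erbb3 and Ncam1 rise (2 adjusted over the list alone) and a camera call (adjusted p = 0.00449; adjusted p = 0.618 with an estimated correlation) that was lost without the 0 h array of replicate 3 (0.113).

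Mef2c rose to 4808 ± 1647 (SD, n = 3) at 48 h (log2 change 2.04, adjusted p = 0.0031). Mef2c changed by 2.66 in replicates 1 and 2 and 0.80 in replicate 3. It was the 1 riser among the 8 muscle transcription factors (1 up and 2 down adjusted over the list alone), 6 of which were lower in replicate 3. Myog had 8455 ± 1754 and Myod1 4720 ± 1411, log2 differences of -0.31 and -0.73 that were not called (adjusted p = 0.28 and 0.11), and the batch fit and replicates 1 and 2 alone called Myod1 lower (adjusted p = 0.0011 and 0.0021). Both that fit and replicates 1 and 2 alone had 1 of the 8 higher and 2 lower. Id3 was the 1 gene that fell among the 15 proliferating myoblast and Notch genes (5 adjusted over the list alone; camera adjusted p = 0.00234; adjusted p = 0.172 with an estimated correlation), of which 8 were lower and 2 higher in replicate 3. In each of the 2 other fits 6 were lower at 48 h (adjusted p = 0.123 with the batch term and 0.0544 in replicates 1 and 2, both with an estimated correlation). The remaining fixed genes were not called without a batch term: Id2 had -1.27, Id1 -1.25, Myf5 -1.05, Acta1 0.50, Myf6 0.36, Igf2 0.17, Chrna1 -0.11, Top2a 0.08, Ccnd1 0.07 and Cdkn1a -0.04 on the log2 scale. Of these, Id2, Id1, Myf5 and Acta1 were called in the batch fit (adjusted p = 0.0014, 8.7e-05, 0.029 and 0.037) and in replicates 1 and 2 alone (0.006, 0.00039, 0.004 and 0.0074). Cell division lists were near their 0 h level, with medians of -0.16 for S phase and -0.08 for mitosis. Limma called 0 of their genes, also when adjusted over the list alone (3 and 1 had an unadjusted p under 0.05), and camera called neither list (adjusted p = 0.151 and 0.702). In the batch fit 2 S phase genes and 1 mitosis gene were lower and camera called the S phase list (adjusted p = 0.0208; adjusted p = 0.572 with an estimated correlation). In replicates 1 and 2 alone 1 gene of each was lower. Both lists were higher in replicate 3. Jun, Junb and Srf, transcription factors of the early response to growth factors, fell among 25 genes of that list (5 adjusted over the list alone; camera adjusted p = 0.0783). Spry1 and Etv5 rose among 13 ERK feedback targets (3 adjusted over the list alone; camera adjusted p = 0.0325; adjusted p = 0.608 with an estimated correlation). The list call was lost without the 0 h array of replicate 1 (0.0856) or 2 (0.112) or the 48 h array of replicate 3 (0.22). Of the early response genes 1 was higher and 6 lower in the batch fit and 3 higher and 7 lower in replicates 1 and 2 alone. Of the ERK feedback targets 4 were higher in the former, and 5 higher and 1 lower in the latter (adjusted p = 0.0888 with an estimated correlation). In replicate 3, 11 early response genes were higher and 2 lower, and 6 ERK feedback targets were higher and 2 lower.

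Limma called 193 A probe sets higher and 99 lower at 48 h than at 0 h, and 90 B probe sets higher and 62 lower. Of the 292 on A, 174 changed at least 2-fold, and over 12446 genes 161 rose and 93 fell. The batch fit called 1329 on A (692 higher, 637 lower) and 709 on B (354 and 355) and kept all 292 and 152. Replicates 1 and 2 alone gave 1678 (808 and 870) and 854 (374 and 480). With each array centred on its median the A split was 127 higher and 128 lower, so the share of rises depends on the scaling and on the fit. The 48 h differences in replicates 1 and 2 and in replicate 3 had r = 0.35 across all tested A probe sets. The A count was 62 and 44 without the 0 h arrays of replicates 1 and 2 and 46 and 54 without their 48 h arrays. On B it was 18 and 11 without the 0 h arrays of replicates 1 and 2, and 48, 15 and 267 without the 48 h arrays of replicates 1, 2 and 3. Of the 59 calls among named genes at 48 h, 23 and 21 were kept without the 48 h arrays of replicates 1 and 2, and of the 123 at 24 h and 48 h together, 58 and 46 without their 0 h arrays.

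A control probe set for 18S ribosomal RNA, which messenger RNA arrays are not meant to measure, was brighter at 48 h than at the other hours. On A its mean intensity was 1428 ± 1693 (SD, n = 3) at 0 h, 2994 ± 2282 at 4 h, 209.8 ± 100.8 at 12 h, 1385 ± 2141 at 24 h and 7543 ± 1149 at 48 h. On B it was 6341 ± 6268 at 0 h and 38490 ± 5258 at 48 h. The ratios of the 3' to the 5' control probe sets, a measure of RNA integrity, were 0.72 to 0.88 for Gapdh and 0.92 to 1.18 for Actb over the arrays.

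**Figure D3:**
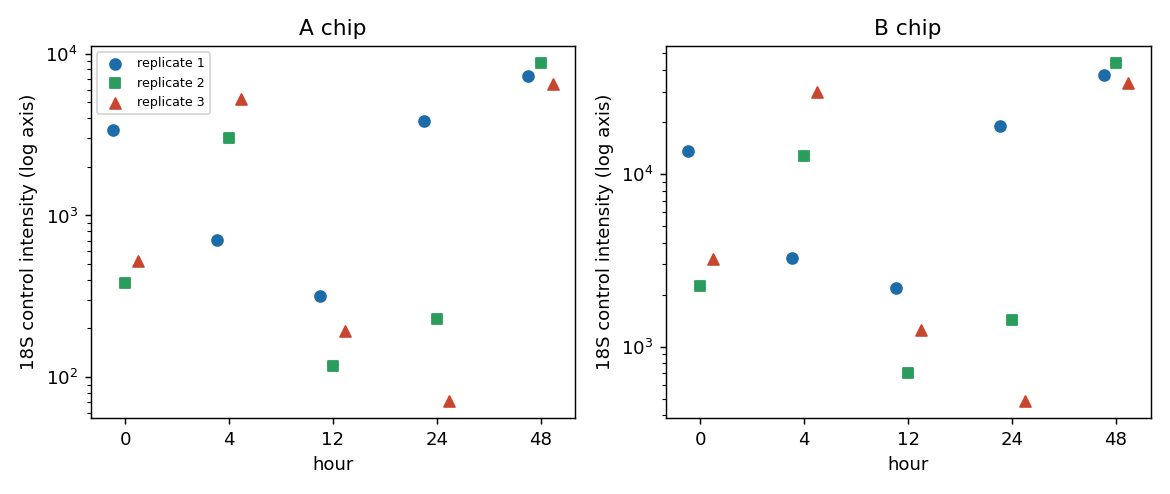
Intensity (log axis) of the 5' control probe set for 18S ribosomal RNA at each hour on the A and the B chip, 1 point per array. At 48 h the 3 arrays lie between 6518 and 8786 on A and between 33710 and 44120 on B, above all other arrays of the same chip.

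**Figure D4:**
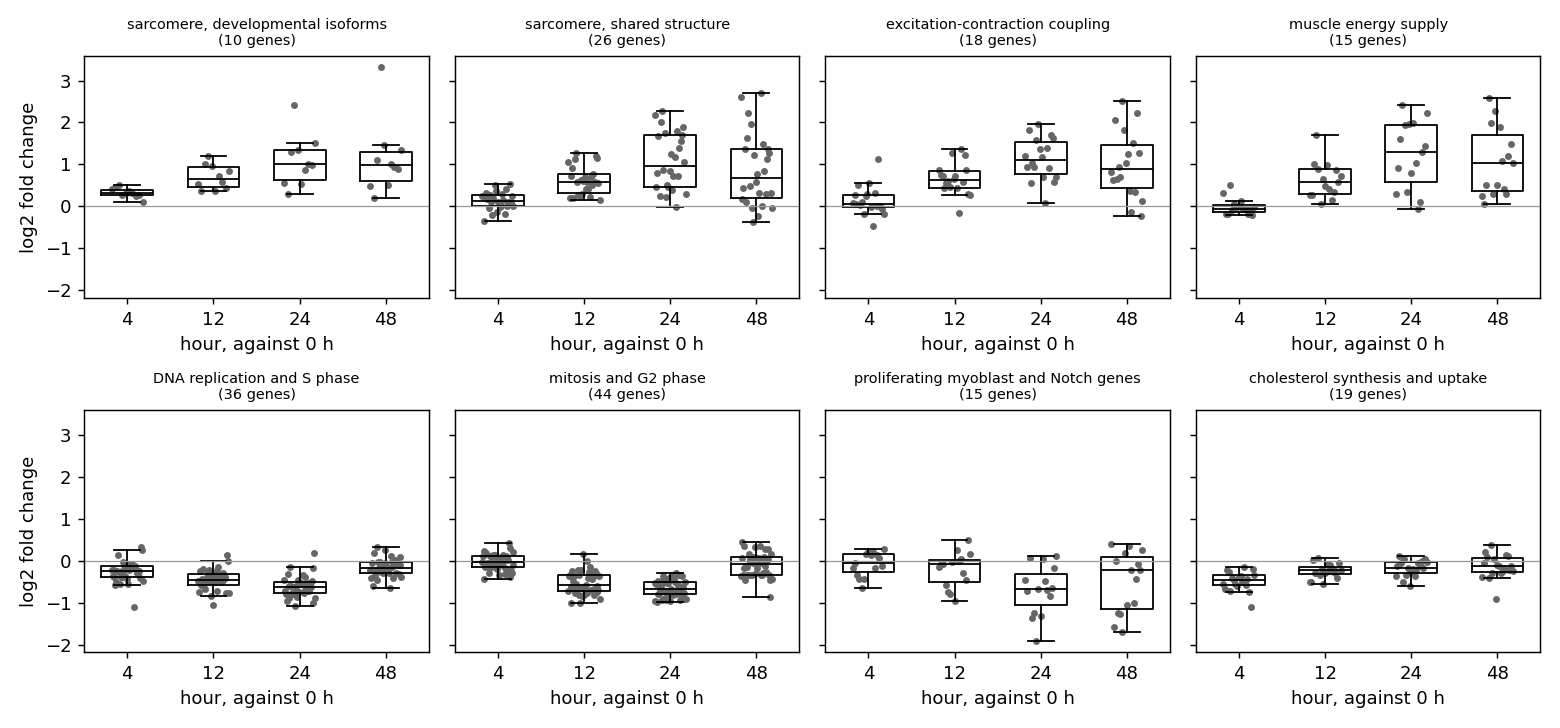
Log2 differences from 0 h (y axis) of the genes of 8 lists at 4, 12, 24 and 48 h; each point is a gene, and the boxes show the median and quartiles. The developmental sarcomere list has medians of 0.33, 0.66, 1.00 and 0.98 at the successive hours, and the mitosis list has -0.03, -0.58, -0.67 and -0.08.

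Between neighbouring hours, few probe sets passed the test. From 4 h to 12 h limma called 0 on A (647 with an unadjusted p under 0.05) and 0 on B (1039). From 12 h to 24 h it called 0 on A (814) and 0 on B (837). Chance alone gives about 679 on A and 675 on B at that unadjusted p. The batch fit found 12 and 2 in the former step and 41 and 6 in the latter, and replicates 1 and 2 alone gave 196 and 15, then 366 and 149. In the latter step the A count was 1 without the 12 h array of replicate 3 or the 24 h array of replicate 2, and the B count 1 without the 24 h array of replicate 1. From 24 h to 48 h, Tagln, an actin-binding protein of smooth muscle, fell from 4082 ± 228.9 to 1607 ± 190.9 (SD, n = 3; A chip, log2 change -1.33, SE 0.16, adjusted p = 0.0085). On the same chip an unnamed probe set rose (log2 change 1.40, adjusted p = 0.041). These A calls and those on B that follow were named after their values were seen. On B, Acta2, the smooth muscle actin gene, fell from 2701 ± 826.6 to 764.5 ± 237.3 (log2 change -1.75, adjusted p = 0.042), and Fst, a secreted inhibitor of activin and myostatin, fell from 11690 ± 2846 to 5705 ± 1212 (-1.02, 0.048). Exoc3l fell from 1473 ± 685.2 to 204.5 ± 52.51 (-2.47, 0.0098), with Mfsd2a and Cdv3 the other falls at -1.17 and -0.68. Rai14 rose from 106.7 ± 39.29 to 621.7 ± 70.12 (2.10, 0.0098), with C130075A20Rik, Ank2, Slc5a3, Mast4 and 7 unnamed probe sets. In total 1 A probe set rose and 1 fell, and 12 B probe sets rose and 5 fell, with 1077 on A at an unadjusted p under 0.05. The batch fit called 349 on A and 349 on B, and replicates 1 and 2 alone gave 628 and 519. Centring each array on its median moved the median difference of all A probe sets to -0.102 and gave 9 rises and 7 falls on B. The A count was 0, 1 and 21 without the 24 h arrays of replicates 1, 2 and 3 and 0, 1 and 0 without their 48 h arrays, and on B the counts were 0, 6 and 106, then 3, 0 and 17.

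Some markers of other cell types were called at 24 h and at 48 h. Over 12446 genes 197 rose and 117 fell at 24 h, and 161 rose and 93 fell at 48 h. For the number tested, calls among the markers were thus not fewer than among all genes. Of 8 smooth muscle and pericyte markers Tagln and Smtn rose at 24 h (2 adjusted over the list alone; camera adjusted p = 0.0325; adjusted p = 0.172 with an estimated correlation). None was called at 48 h (none adjusted over the list alone; adjusted p = 0.234). The camera call at 24 h was lost without the 0 h array of replicate 1 (0.0609) or 3 (0.064) or the 24 h array of replicate 3 (0.112), and in the batch fit (0.152). Of 5 adipocyte markers Cd36 rose and Cebpa fell at 48 h (1 and 1 adjusted over the list alone). Erbb3, which is also in the acetylcholine receptor list, was the 1 of 6 Schwann and neural markers that rose at 24 h and at 48 h. At 48 h the batch fit had 1 of them higher and 1 lower, and replicates 1 and 2 alone 3 higher and 1 lower (median 0.99; camera adjusted p = 0.00842; adjusted p = 0.186 with an estimated correlation). Col2a1 fell at both hours among 3 cartilage and bone markers. Of the fibroblast, endothelial, and macrophage and leukocyte markers on the chips, 4 of 13, 5 of 13 and 4 of 14 passed the intensity filter and were tested. In the fit over all arrays without a batch term, none of these was called at any hour, over all probe sets or adjusted over the list alone, and 1 fibroblast marker, at 48 h, had an unadjusted p under 0.05. The other fits differ: with the batch term 1 of 4 fibroblast markers was lower at 24 h, and in replicates 1 and 2 alone 1, 3 and 2 were lower at 12, 24 and 48 h (medians -0.23, -1.03 and -0.52). In each of these fits 1 of 5 endothelial markers was lower at 48 h and, adjusted over the list alone, 1 was higher at 12 h. Adjusted over the list alone, replicates 1 and 2 also had 1 of 4 macrophage and leukocyte markers lower at 48 h. Of the smooth muscle and pericyte markers both fits had 2 higher and 1 lower at 24 h, and at 48 h the batch fit had 1 lower and replicates 1 and 2 had 1 higher and 2 lower. Of the 35 markers, 9 were lower and 6 higher in replicate 3 than in replicates 1 and 2.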

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

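Of the tests in this part, those of single arrays, of RNA outside annotated messages, of muscle cell share and of dividing cells were chosen after the results were seen. The tests of array scaling, of the stage of the time course and of ribosomal RNA as the origin of the 48 h changes were planned before.

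Control probe sets for 18S ribosomal RNA were bright at 48 h on both chips, a signal outside the comparisons of messenger RNA. Of the 64 control probe sets shared by the chips, the 5' and the 3' 18S probe sets were the ones with all 3 arrays at 48 h above all arrays at 0 h and a mean at least 4-fold higher on both chips. The 5' probe set had a mean intensity of 7543 at 48 h and 1428 at 0 h on A, and 38490 and 6341 on B, and the 3' probe set had 3948 and 453.2 on A and 19890 and 2466 on B.

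The tables argue against a fault of single arrays as the origin of the 18S signal, since over the 15 labels the 5' probe set on A and on B had Spearman's rho = 1 and Pearson's r = 0.997 (permutation p = 1e-05 for each, the smallest that the permutations can give). Without the 2 labels farthest from the median r was 0.996. Whether the ribosomal RNA signal set all of the 48 h gene changes stays open. Within-hour deviations of the signal and of the shift towards the 48 h pattern were compared over 12 A arrays of 0 to 24 h. They had r = 0.18 (95% interval -0.55 to 0.75) and rho = 0.21 (permutation p = 0.62), an interval too wide to decide. In a comparison made after the results were seen, the A signal was 1428 ± 1693 (SD, n = 3) at 0 h and 1385 ± 2141 at 24 h. Median log2 differences of the developmental, fast, shared structure, coupling and energy lists were 1.00, 1.20, 0.95, 1.11 and 1.29 at 24 h. At 48 h they were 0.98, 1.21, 0.69, 0.89 and 1.04. For the rise of these lists, already present at 24 h, this argues against the signal as the origin. More RNA outside annotated messages at 48 h also stays open: among B probe sets called at 48 h, 28.9% of the higher ones (26 of 90) and 4.8% of the lower ones (3 of 62) were unnamed (Fisher's exact p = 0.00013), while 28.4% of all tested ones were, so it is the lower ones that depart from the tested share. A change in the cultures at 48 h, the difference the design names, remains open and untested.

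The arrays of replicate 3 stood apart at every hour, and against array-wide scaling as the origin, 4623 A probe sets still differed after quantile normalization, where 4606 had with the deposited scaling. A lower share of muscle cells stays open. Of 35 markers of other cell types 9 were lower in replicate 3 and 6 higher, but fewer muscle cells need not raise every such marker. Among the 9 was Des, which is also in the shared sarcomere structure list, where 12 of 26 genes were lower and 3 higher. The replicate 3 difference and the 24 h change of replicates 1 and 2 had r = -0.17 (rho = -0.20) across A probe sets, which are not independent replicates. That argues against a different stage of the time course as the origin of the whole split. Whether stage makes up a part of it stays open, since this r covers a single contrast and all tested probe sets. More dividing cells in replicate 3 is a candidate explanation for part of the split, with 77 of 80 S phase and mitosis genes higher, but genes such as Crabp1, at 17.09 in replicates 1 and 2 and 2059 in replicate 3, lie outside it. No group of the design separates replicate 3, and another source of cells or another day remain open and untested.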

How the results depend on the processing

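The fits with replicate 3 as a batch term and with replicates 1 and 2 alone were chosen after the data were seen, and all other alternatives were planned. No probe set called at 24 h or 48 h against 0 h changed direction under quantile normalization or median centring. The batch term could not change a direction, since every hour has a replicate 3 array and the log2 changes stay the same. On A 317 of 362 calls at 24 h and 282 of 292 at 48 h were kept under quantile normalization, and 322 and 226 under median centring. Of 123 calls among the named genes, quantile normalization ended 6 and added 6, median centring ended 5 and added 8, the smaller pseudocount changed none and testing all probe sets ended 14. Of 633 results from other probe sets of named genes, 585 were the same, 33 lost the call, 13 gained one and 2 reversed. Of 51 list calls, the batch term kept 48 and added 8, replicates 1 and 2 alone kept 44 and added 19, and quantile normalization kept 43 and added 2. Testing all probe sets kept 49, the mean of a gene's probe sets kept 46, and leaving out the 0 h array of replicate 3 kept 36. The number of arrays and the difference of replicate 3 limit the calls, and dim probe sets, near the pseudocount, have understated changes. Where a cause is not given, the cause was not tested.

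With replicate 3 as a batch term, calls on A were 143 at 12 h against 0 h (0 without it), 1770 at 24 h (362), 1329 at 48 h (292), and 12 at 12 h against 4 h (0). They were 41 at 24 h against 12 h (0), 349 at 48 h against 24 h (2) and 1895 over time (267). On B they were 44 (1), 556 (115), 709 (152), 2 (0), 6 (0), 349 (17) and 898 (121) in the same order, and 258 results of named genes were called (123). Replicates 1 and 2 alone gave 24 on A at 4 h against 0 h (0) and, in the order above, 568, 2036, 1678, 196, 366, 628 and 2376 on A, 84, 696, 854, 15, 149, 519 and 1059 on B, and 296 results of named genes. By construction replicates 1 and 2 alone leave replicate 3 out of the spread. The batch term takes out its mean difference over the hours, not a different change between hours. On A, probe sets called at 24 h in replicates 1 and 2 had a median absolute log2 change of 0.81 there and 0.35 in replicate 3. At 48 h the values were 0.80 and 0.33. The direction was the same for 83.4% at 24 h and 73.5% at 48 h. Picking probe sets by their calls in replicates 1 and 2 by itself favours larger changes there.

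The replicate numbers were not taken to pair the arrays, since not every same-numbered pair had r over 0.1, although every pair of number 3 did on both chips. Same-numbered arrays deviated from their hour means with r from 0.04 to 0.62 for number 1, 0.12 to 0.46 for number 2 and 0.48 to 0.73 for number 3 on A. On B the ranges were 0 to 0.23, 0.04 to 0.20 and 0.23 to 0.43. With the replicate number as a block the counts on A were 96, 1663, 1223, 1, 33, 293 and 1637 in the order above, on B 24, 487, 660, 2, 3, 302 and 779, and 235 results of named genes were called.

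Array quality weights gave 152 on A at 12 h against 0 h, 2392 at 24 h, 1257 at 48 h, 1174 at 24 h against 12 h, 934 at 48 h against 24 h and 2851 over time. On B they gave 5, 328 and 757 against 0 h, 178 at 48 h against 24 h and 631 over time; the cause was not tested. Only the arrays of the hours compared, by construction fewer arrays, gave 171 on A at 24 h and 54 at 48 h against 0 h and 0 at 48 h against 24 h. On B they gave 0 at 12 h, 59 at 24 h and 22 at 48 h against 0 h and 0 at 48 h against 24 h. Without the intensity trend B had 0 at 12 h, 66 at 24 h, 99 at 48 h, 5 at 48 h against 24 h and 78 over time. A threshold of 2-fold, which by construction removes small changes, left 187 on A at 24 h and 174 at 48 h.

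On scaling, quantile normalization gave 1 on A at 24 h against 12 h and 1 at 48 h against 24 h, and median centring gave 1 and 7. With 0.5 times the pseudocount 1 was called on A and 9 on B at 48 h against 24 h. A pseudocount 4 times as large gave 2 on A at 12 h against 0 h, 2 on A at 24 h against 12 h and 27 on B at 48 h against 24 h. A pseudocount of 1 gave 1 on A at 24 h against 12 h, 1 on A at 48 h against 24 h and 0 on B at 12 h against 0 h. On the filter, testing all probe sets gave 2 on A and 0 on B at 12 h against 0 h and 4 on B at 48 h against 24 h. The upper 40% gave 1 on A and 27 on B at 48 h against 24 h. With an estimated correlation 0 of the 51 list calls held, and 0 of the 56 with the batch term, whereas 21 of the 63 in replicates 1 and 2 alone held.

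Leaving out 1 array at a time gave the following lowest and highest counts. These fits had no batch term, so an array left out changes the weight of replicate 3 at its hour, and the counts carry that difference too. On A they were 0 and 1 at 12 h against 0 h, 60 and 636 at 24 h, 44 and 431 at 48 h, 0 and 1 at 24 h against 12 h, 0 and 21 at 48 h against 24 h and 81 and 393 over time. On B they were 0 and 1, 34 and 211, 11 and 267, 0 and 1, 0 and 106, and 30 and 195 in the same order. At 4 h against 0 h and 12 h against 4 h limma called 0 on both chips with each array left out. With all arrays 671 and 647 on A and 732 and 1039 on B had an unadjusted p under 0.05. Chance alone gives about 679 on A and 675 on B. Named genes had 46 to 130 calls and lists 40 to 59.

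Results that reversed were few. Oxidative phosphorylation at 4 h had camera adjusted p = 0.0311 upwards and 0.331 downwards with quantile normalization. Ribosomal proteins had 4.09e-12 and 0.606 at 4 h and 0.0336 and 0.141 at 12 h in the same way. S phase genes at 4 h had 0.00459 downwards, and with 1 array left out the values ran from 2.86e-08 (without the 4 h array of replicate 3) to 0.984 (upwards, without the 0 h array of replicate 3). Leaving out either array keeps replicate 3, where these genes were higher, on only 1 side of the comparison. For Ncam1 at 48 h the probe set used had a log2 change of 1.02 and other probe sets -0.42 and -0.09; the cause was not tested.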

Other observations

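Several lists described here had few or no called genes. The 45 oxidative phosphorylation genes had 0 calls in limma at 24 h and 48 h, also when adjusted over the list alone (4 and 2 had an unadjusted p under 0.05), with medians of 0.07 and -0.02. Camera called a shift at 24 h (adjusted p = 0.00804; adjusted p = 0.716 with an estimated correlation), which was lost under quantile normalization (0.248) and without the 0 h array of replicate 1 (0.0682). Of 17 genes of the unfolded protein response Herpud1, a gene of protein degradation at the endoplasmic reticulum, rose at 24 h (4 adjusted over the list alone; camera adjusted p = 0.00122; adjusted p = 0.172 with an estimated correlation). None was called at 48 h. Of 20 genes of glycolysis and hypoxia P4ha1, a collagen hydroxylase, rose and Hk1, a hexokinase, fell at 24 h (4 up and 1 down adjusted over the list alone; camera adjusted p = 0.148). The Hk1 call was lost under quantile normalization (adjusted p = 0.051) and median centring (0.074). Of 17 genes of the TGF-beta and BMP response Tgfb3 rose and Smad6, an inhibitor of BMP signalling, fell at 24 h (2 up and 2 down adjusted over the list alone; camera adjusted p = 0.817). Of 13 interferon response genes H2-D1 fell at 24 h (4 adjusted over the list alone; camera adjusted p = 0.124), and its call was lost under quantile normalization (0.051), median centring (0.056) and no filter (0.067). In the batch fit at 24 h 1 oxidative phosphorylation gene, 5 unfolded protein response genes and 3 glycolysis and hypoxia genes were higher (1 of the last list lower). TGF-beta and BMP genes had 2 higher and 3 lower, and interferon genes 6 lower. Replicates 1 and 2 alone gave 1, 4, 5 (1 lower), 2 (5 lower) and 4 lower in the same order, and at 48 h 2 unfolded protein response genes higher. Replicate 3 had 3 oxidative phosphorylation genes lower, 2 unfolded protein response genes higher and 2 lower, 7 glycolysis and hypoxia genes higher and 1 lower, 6 TGF-beta and BMP genes higher and 3 lower, and 6 interferon genes higher.

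Slc7a5 was the 1 amino acid response gene of 20 that rose at 48 h (1 adjusted over the list alone; camera adjusted p = 0.00234; adjusted p = 0.668 with an estimated correlation). That list call was lost without the 48 h array of replicate 3 (0.926) and in replicates 1 and 2 alone (0.438). The heat shock genes Hspb7, Hspb3 and Hspb2 rose at 48 h with log2 changes of 1.95, 1.65 and 1.26 (3 adjusted over the list alone). The median of that list of 15, -0.03, and its mean, 0.29, differ in sign, and camera did not call it (adjusted p = 0.168), though it did in replicates 1 and 2 alone (0.0494; adjusted p = 0.174 with an estimated correlation). At 24 h and 48 h, over all arrays without a batch term, limma called 0 genes, also when adjusted over the list alone, among 26 of collagen and extracellular matrix, 11 of matrix proteases and inhibitors, 14 of the insulin-like growth factor axis, 17 of FoxO targets and autophagy and 13 of the circadian clock. The same held for 29 of ribosome biogenesis, 25 cytosolic ribosomal proteins, 19 of cholesterol synthesis, 12 of fatty acid synthesis and 18 of cell cycle exit. At each hour 0 to 5 genes of each of these lists had an unadjusted p under 0.05. With the mean replicate 3 difference taken out, or replicate 3 left out, several of these lists had calls. In the batch fit at 24 h 6 fatty acid synthesis genes were lower (camera adjusted p = 0.000709; adjusted p = 0.207 with an estimated correlation), cell cycle exit had 3 higher and 3 lower, and matrix proteases 2 and 2. The insulin-like growth factor axis had 1 and 2, FoxO targets 1 and 4, the circadian clock 1 higher, and ribosome biogenesis and ribosomal proteins 1 lower each. At 48 h it called 5 collagen and matrix genes and 3 ribosome biogenesis genes higher, 2 proteases higher and 2 lower, and 2 insulin-like growth factor axis genes higher and 2 lower. It also called 3 FoxO targets, 3 cell cycle exit genes, 1 fatty acid synthesis gene and 1 cholesterol gene lower and 1 clock gene higher. In replicates 1 and 2 alone 7 fatty acid synthesis genes were lower at 24 h (camera adjusted p = 1.96e-05; adjusted p = 0.059 with an estimated correlation), with 6 collagen and matrix genes and 2 cholesterol genes. At 24 h they also had 2 proteases higher and 4 lower, 1 FoxO target higher and 4 lower, 3 cell cycle exit genes higher and 2 lower, and 2 insulin-like growth factor axis genes higher and 2 lower. The clock had 1 gene higher and ribosome biogenesis 1 lower. At 48 h they had 4 collagen and matrix genes higher and 9 lower, 2 proteases higher and 6 lower, and 1 insulin-like growth factor axis gene higher and 3 lower. Fatty acid synthesis, FoxO targets and cell cycle exit had 3 lower each, ribosome biogenesis 2 higher and the clock 1 higher. Of these lists, in replicate 3 the insulin-like growth factor axis had 10 of 14 genes lower and 3 higher, FoxO targets 10 of 17 lower, fatty acid synthesis 9 of 12 higher and 1 lower, and ribosome biogenesis 13 of 29 higher. Collagen and matrix had 12 higher and 5 lower, proteases 3 higher and 5 lower, cell cycle exit 5 higher and 9 lower, cholesterol synthesis 14 higher and the clock 1 higher.

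Of the tests in this paragraph and the next, those of dilution and of the return of cell division genes were chosen after the results were seen, and the count of other splits was planned. Cell division genes had lower means at 24 h than at 0 h and were back near the 0 h level at 48 h. From 24 h to 48 h the S phase and mitosis lists had median log2 differences of 0.44 and 0.58 with 0 genes called in limma without a batch term (0 and 3 had an unadjusted p under 0.05) and 21 called higher with replicate 3 as a batch term. Camera gave unadjusted p = 3.1e-05 and 1.7e-07 (p = 0.37 and 0.33 with an estimated correlation), and with the batch term 1.8e-14 and 8.1e-22 (p = 0.025 and 0.017 with an estimated correlation). Whether that return held in each replicate stays open. In replicates 1, 2 and 3, 92.5%, 97.5% and 80% of the 80 genes were higher at 48 h than at 24 h. The lowest, 80%, falls short of the 90% set for each replicate. These shares come from the arrays in which the return was seen, so they are no separate evidence for it. That dividing cells diluted the muscle cells at 48 h stays open too: 82 muscle structure and energy genes had a median difference of -0.09 over all replicates, a test run before the split by replicate, and medians of 0.11, 0.01 and -0.42 in replicates 1, 2 and 3 (quartiles -0.62 and -0.22 in replicate 3).

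Other splits of the same arrays into groups of the same sizes were counted for each comparison. For any change over time, 1 of 100 splits, the real one, called as many, 267 on A (highest other 175) and 121 on B (highest other 41). A chance assignment of these arrays to the hours is thus an unlikely origin of those counts. Chance differences between cultures are not addressed, since the labels do not say that replicates were separate cultures. In 100 splits that kept 1 array of replicate 3 in each group, a test added after the results were seen, the highest other counts were 77 and 22. Each comparison of 3 arrays with 3 has 10 splits, too few for a share under 0.05. The real split and the highest other called 362 and 0 at 24 h against 0 h on A, 115 and 0 on B, 292 and 0 at 48 h on A, and 152 and 0 on B. They called 2 and 1 at 48 h against 24 h on A, 17 and 1 on B, and 1 and 0 at 12 h against 0 h on B. At 4 h against 0 h on both chips, at 12 h against 0 h on A, at 12 h against 4 h on A and at 24 h against 12 h on both chips all splits called 0. At 12 h against 4 h on B the real split called 0 and the highest other 123. There the 4 h arrays of replicates 1 and 2 and the 12 h array of replicate 2 stood against the replicate 3 arrays of both hours and the 12 h array of replicate 1. That grouping partly separates replicate 3 from the others, and whether this gave the count was not tested.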
